A study of Mus musculus with 6 samples.

How the data were processed

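RNA was measured in 6 subcutaneous tumours grown in male C57BL/6 mice from H22, a mouse hepatocellular carcinoma cell line. The 3 lenvatinib-sensitive tumours came from control mice. The 3 lenvatinib-resistant tumours came from mice given lenvatinib, an inhibitor of several receptor tyrosine kinases, at 100 mg/kg per day by intraperitoneal injection on 2 days a week, over 2 cycles, per the labels' protocols. The series design calls the 3 tumours of a group biological replicates. The labels are not of one piece on the drug: the treatment field reads as untreated for all 6 tumours, and the protocol names lenvatinib as well as its solvent for the control mice. Groups were taken from the sample titles.

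Total RNA was extracted with TRIzol and libraries were made with a Vazyme VAHTS Universal V6 kit, per the labels' protocols. Whether the libraries kept the strand is not given in the sources used here. The submitters' processing notes name HISAT2, StringTie and edgeR, without versions or the step each was used for. The genome build, the gene annotation and the rule for reads that match several genes are not given in the sources used here.

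The authors deposited 2 tables of 20482 genes with a column per tumour. The first table holds read counts per gene, deposited as whole numbers with no normalization. The second holds FPKM, which the authors made by dividing counts by gene length and by the total count. Over 5442 genes with at least 500 counts in every tumour, the ratio of count to FPKM differed between tumours by a constant factor, to within a relative 1.73e-06. Every listed gene has at least 2 counts over the 6 tumours, and no row lacks a gene. Of the identifiers, 20355 (99.4%) were found in GENCODE mouse release 21, which uses build GRCm38. Coordinates and gene types come from that annotation by identifier. The spreadsheet had turned 24 gene symbols into dates, and the identifiers gave all 24 back.

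Total counts ran from 15995403 to 17545098 per tumour, a ratio of 1.10, so that 3 counts correspond to 0.171 to 0.188 CPM, that is, counts scaled to a common library size. No 2 libraries agreed within sampling noise: the chi-square per gene between 2 tumours, over genes with at least 20 counts in the pair, was 38.5 or more.

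Genes were tested with edgeR 4.0.16 in R 4.3.3: filtering by filterByExpr, TMM scaling and the quasi-likelihood F-test, with no block. The fit compared the 3 resistant with the 3 sensitive tumours, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are resistant minus sensitive, with the standard error (SE) from the fold change and its F statistic. CPM values per tumour use the TMM-scaled library sizes and are given as mean ± SD, except that the lymph node genes of the closing section are scaled by the total count alone. Before the data were examined, 58 gene lists were fixed (38 of pathways, 16 of cell types and 4 of RNA quality), and the 56 with at least 5 tested genes were tested with camera of limma 3.58.1. This used log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, with adjustment over the lists. Camera with the correlation estimated per list and the rotation test fry were run beside it. The 4 lists of RNA quality hold mitochondrially encoded, ribosomal protein, immediate early and replication-dependent histone genes. A list's score in a tumour is the mean of its genes' log2 CPM, each centred over the 6 tumours. Scores were compared by an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1.

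The rule for named genes was fixed at the same time. It takes up to 12 genes per direction past the threshold or, since none passed, the 6 with the smallest p per direction, with a mean log2 CPM of at least 1 and a named symbol. The conditions on level and symbol were written for genes past the threshold and were applied here as well. The rule also takes the tested receptors that lenvatinib inhibits, and up to 4 members with the smallest p from each list described. Some genes that the rule takes are not reported here. Trbd1 and the single muscle, fat, lymphocyte and oncofetal genes given per tumour (Acta1, Adipoq, Cd3e, Afp and Gpc3, each a member of a fixed list) were chosen after their values were seen. The lymph node genes of the closing section lie outside the rule and were chosen before their values were read.

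On counts simulated from the means, library sizes and dispersions of this comparison (14139 genes, the changed ones with a mean count above 50), the test called 6 of 50 genes changed 2-fold, 32 of 50 changed 4-fold, 42 of 50 changed 8-fold and 47 of 50 changed 16-fold, with 7 false calls. On simulated log2 values, camera with the preset correlation called a list shifted by 1 log2 unit, and 0 of the 56 lists where nothing was shifted. Those values were drawn gene by gene, so they hold no correlation between genes.

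The alternatives were RLE, upper quartile and library-size scaling, DESeq2 1.42.0, limma-voom, edgeR's exact test, filters on low counts, the deposited FPKM with limma-trend at pseudocounts of 1 and 0.1, a minimum absolute log2 fold change of 1, a block on the replicate number, and leaving out each tumour in turn. Robust dispersions, sample quality weights, leaving out immunoglobulin and T cell receptor genes or mitochondrially encoded genes, and a correction of each library for its trend with gene length and GC content were added after seeing the data. Length came from the count to FPKM ratio and GC content from the longest GENCODE transcript, and 99.7% of the tested genes had both. Of the 68 genes named by the rule in the text, 21 share an exon stretch with another annotated gene, 10 of them on the same strand, so their counts depend on how such reads were assigned. Ribosomal protein genes have many processed pseudogenes and the globin genes have near-identical copies, and their counts carry the same doubt.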

Results

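Gene expression was profiled by RNA sequencing in 3 lenvatinib-sensitive and 3 lenvatinib-resistant H22 tumours, to find the genes and pathways that differ between them. The sensitive tumours came from control mice, so the drug itself and the resistance cannot be told apart. H22 is a mouse hepatocellular carcinoma line, here grown under the skin, so each sample holds tumour cells together with the vessels, immune cells and other host tissue around them. Total counts per tumour were 17545098, 17106568 and 17390837 in sensitive tumours 1 to 3 and 16433284, 16635385 and 15995403 in resistant tumours 1 to 3. Depth differed little, with a ratio of highest to lowest of 1.10, but every sensitive total lay above every resistant one.

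Resistant tumours carried less RNA of T cells, natural killer cells and the interferon gamma response, and less mitochondrially encoded RNA. They carried more RNA of ribosomal proteins, nuclear oxidative phosphorylation subunits and cholesterol synthesis enzymes. These differences were called over lists of genes with a preset correlation between genes, not with an estimated one. The lists of mitochondrially encoded and ribosomal protein genes were fixed as lists of RNA quality, which was not tested as a cause. No single gene passed the per-gene threshold in edgeR's quasi-likelihood test, while DESeq2 called 117 and edgeR's exact test 42. The T cell median log2 fold change went from -3.56 to -1.15 without sensitive tumour 2. The mitochondrial median went from -0.92 to -0.35 without sensitive tumour 1. For T cells and interferon gamma, a part of sensitive tumour 2 alone and a group difference cannot be told apart. By the p of the quasi-likelihood test, the clearest named genes were Tmem168, Rab22a and Ywhah, which were lower in resistant tumours, and Per1, a core gene of the circadian clock, which was higher.

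Of 14392 genes tested, 0 had an adjusted p under 0.05 by edgeR's quasi-likelihood test, and the smallest adjusted p was 0.191. At an unadjusted p under 0.05 there were 1404 genes, 579 higher and 825 lower in resistant tumours, where 719.6 are expected by chance on average. Other splits of the 6 tumours into 3 and 3 gave 148 to 2593 such genes, so the excess does not by itself tie them to the groups. Limma-voom also called 0 genes, while DESeq2 called 117 (48 higher, 69 lower) and edgeR's exact test called 42 (11 higher, 31 lower), with 31 genes called by both. In 2296 genes (15.95%) the 3 values of one group all lay above those of the other, where chance gives 10% on average. This share was not counted for other splits. The biological coefficient of variation was 0.402 and the median SE of a log2 fold change was 0.26. The unadjusted count moved by more than 1.5 times when single tumours were left out: it was 934 without sensitive tumour 2, 2666 without sensitive tumour 3, 631 without resistant tumour 1, 920 without resistant tumour 2 and 834 without resistant tumour 3.

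Tmem168 (ENSMUSG00000029569, GRCm38 chromosome 6, 13580687 to 13608100), which encodes a membrane protein, stood at 82.4 ± 11.2 CPM in sensitive and 28.9 ± 1.01 CPM in resistant tumours (SD, n = 3 each). Its log2 fold change was -1.51 ± 0.15 (SE), with an adjusted p of 0.191 by edgeR. Rab22a, a small GTPase of endosomal traffic (ENSMUSG00000027519, chromosome 2, 173659760 to 173707343), stood at 92.8 ± 11.3 and 32.3 ± 2.95 CPM, a log2 fold change of -1.52 ± 0.15 with the same adjusted p. Ywhah, a 14-3-3 adaptor protein (ENSMUSG00000018965, chromosome 5, 33018816 to 33027966), stood at 281.3 ± 27.8 and 122.1 ± 10.6 CPM, a log2 fold change of -1.20 ± 0.13 (adjusted p = 0.230, edgeR). Vma21, an assembly factor of the proton pump of lysosomes (ENSMUSG00000073131, chromosome X, 71815924 to 71839757), had a log2 fold change of -1.13 ± 0.17. Cd300e, a receptor of myeloid cells (ENSMUSG00000048498, chromosome 11, 115051917 to 115062177), had one of -2.65 ± 0.38 from a low level, 4.16 ± 0.53 against 0.65 ± 0.16 CPM. In the other direction, Per1 (ENSMUSG00000020893, chromosome 11, 69095217 to 69109960) stood at 35.1 ± 4.16 CPM in sensitive and 77.6 ± 1.55 CPM in resistant tumours, a log2 fold change of 1.15 ± 0.14 (adjusted p = 0.332, edgeR). The neighbouring genes Crip2 (ENSMUSG00000006356, chromosome 12, 113140236 to 113145506) and Crip1 (ENSMUSG00000006360, chromosome 12, 113146316 to 113153879), both encoding cysteine-rich LIM domain proteins, had log2 fold changes of 1.10 ± 0.18 and 1.31 ± 0.18. Tppp3, a tubulin-binding protein gene (ENSMUSG00000014846, chromosome 8, 105467493 to 105471526), had one of 1.71 ± 0.29. For these genes all 3 tumours of one group lay above all 3 of the other, and DESeq2 and the exact test called each of them. The genes were picked by smallest p in the same tumours, so neither point is separate support. None of these genes passed in the quasi-likelihood test, where Vma21, Cd300e, Crip1, Crip2 and Tppp3 had an adjusted p of 0.509 or 0.510.

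**Figure D1:**
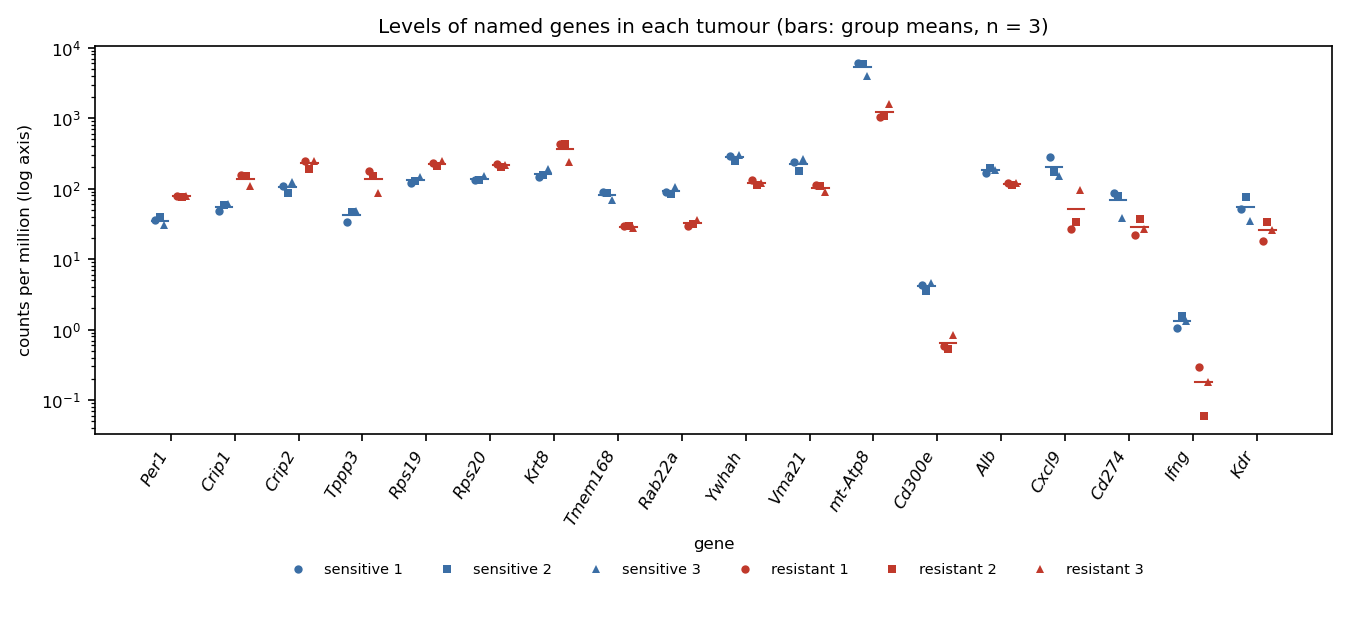
Counts scaled to a common library size (CPM) on a log axis for 18 named genes in each of the 6 tumours, with sensitive tumours in blue, resistant tumours in red, the marker shape giving the tumour number and a bar at each group mean. Tmem168 sits between 69.6 and 90.4 CPM in the sensitive tumours and between 27.7 and 29.6 CPM in the resistant ones, and Per1 between 30.7 and 39.0 against 75.9 and 78.8 CPM.

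Of the 56 gene lists tested, camera with the preset correlation called 25, 10 higher and 15 lower in resistant tumours. With the correlation estimated per list it called 0, the smallest adjusted p being 0.708. In the called lists the estimates ran from 0.011 (drug metabolism) to 0.98 (fat cells). They were 0.93 for T cells, 0.67 for mitochondrially encoded genes, 0.63 for interferon gamma and 0.31 for ribosomal proteins. The small p values with the preset 0.01 thus rest on a near-independence between genes that most of these estimates go against. Fry called 0 for a shift in one direction (smallest FDR 0.256). Fry's test for change in either direction called 1, the replication-dependent histones (FDR 0.0252). In several called lists no member passed edgeR's quasi-likelihood test even when adjusted over the list alone. Among these were nuclear oxidative phosphorylation, cholesterol synthesis, CD8 T and natural killer cells, type I interferon, checkpoints and both MHC classes. In 14 lists the scores of the 3 tumours of one group all lay above those of the other, which gives an exact permutation p of 0.1, the smallest that 3 against 3 can reach. Each of the 10 ways to split the 6 tumours into 3 and 3 called at least 8 lists with the preset correlation, and the highest called 30. On log2(FPKM + 1), where the pseudocount shrinks differences between low values, no call was lost, but several medians were smaller in size: -2.14 for B and plasma cells, -1.38 for T cells, -0.99 for CD8 T and natural killer cells, -0.61 for dendritic cells, -0.57 for checkpoints, 0.31 for erythroid genes, -0.16 for the receptors of lenvatinib, -0.12 for hepatocyte genes and -0.07 for drug metabolism. Those of the cell cycle, serine and MYC lists were larger there (0.27, 0.26 and 0.25).

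T cell genes were lower in resistant tumours in 16 of 16 tested members, with a median log2 fold change of -3.56 (camera adjusted p = 1.1e-07, and adjusted p = 0.708 with an estimated correlation). Examples are Il2ra, the interleukin 2 receptor alpha chain, at 10.4 ± 8.0 against 1.65 ± 0.59 CPM, Foxp3, the transcription factor of regulatory T cells, at 8.77 ± 10.3 against 0.75 ± 0.38 CPM, and Trac, the constant region of the T cell receptor alpha chain, at 25.6 ± 34.2 against 2.20 ± 1.01 CPM. In edgeR's quasi-likelihood test none of the 16 passed over all genes tested, and 13 passed when adjusted over the list alone. DESeq2 called 8 of them over all genes. The SDs show that sensitive tumour 2 sets most of this size: Cd3e stood at 41.2 CPM there, at 5.58 and 2.46 CPM in the other sensitive tumours, and at 0.48, 0.84 and 2.68 CPM in the resistant ones. Without sensitive tumour 2 all 16 members were still lower, with a median of -1.15 (camera adjusted p = 2.0e-07). The list of CD8 T and natural killer cells was lower in 17 of 17 members, with a median of -2.28 (adjusted p = 7.5e-07 by camera, 0.708 as the adjusted p with an estimated correlation) and of -1.21 without sensitive tumour 2. Its natural killer cell receptors Klrd1 and Ncr1 had log2 fold changes of -2.39 ± 0.78 and -2.78 ± 0.95, and Klrd1 one of -1.22 without sensitive tumour 2. Ifng, the gene of interferon gamma itself (ENSMUSG00000055170, chromosome 10, 118441046 to 118445892), was read at 1.05, 1.55 and 1.31 CPM in the sensitive tumours and at 0.30, 0.06 and 0.18 CPM in the resistant ones, where 3 counts are about 0.18 CPM.

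Genes that interferon gamma induces were lower in 17 of 19 tested members, with a median log2 fold change of -1.36 (camera adjusted p = 9.2e-08, and adjusted p = 0.708 with an estimated correlation). By edgeR's quasi-likelihood test 4 passed when adjusted over the list alone and none over all genes, where DESeq2 called 3. Cxcl9, a chemokine that draws T cells (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), stood at 281.3, 170.6 and 151.2 CPM in the sensitive tumours and at 27.2, 33.7 and 95.4 CPM in the resistant ones, a log2 fold change of -1.95 ± 0.52. Cxcl10 had one of -1.36 ± 0.36, the guanylate-binding protein gene Gbp4 one of -2.34 ± 0.55, and Cd274, which encodes the checkpoint ligand PD-L1 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), one of -1.27 ± 0.35. Without sensitive tumour 2 the list's median was -1.11. The type I interferon list was lower in 22 of 23 members (median -0.87, camera adjusted p = 2.8e-06, estimated-correlation adjusted p = 0.728). Bst2 was its exception, with a log2 fold change of 0.44 ± 0.11, or 0.15 with the length and GC correction. The list's median was -0.50 without sensitive tumour 2.

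Immune checkpoint genes were lower in 17 of 20 members (median -1.15, camera adjusted p = 2.5e-05, adjusted p = 0.708 with an estimated correlation), among them Icos at -3.02 ± 0.82 and Ctla4 at -2.84 ± 0.93 on the log2 scale. MHC class II genes were lower in 8 of 8 members (median -1.94, camera adjusted p = 0.00018, adjusted p = 0.708 with an estimated correlation), with Cd74, the invariant chain, at 1075 ± 911 against 240.4 ± 172.4 CPM, H2-Ab1 at 371.8 ± 312.7 against 96.8 ± 69.5 CPM, and Ciita, the transactivator of these genes, at 44.3 ± 56.3 against 5.40 ± 4.70 CPM. Without sensitive tumour 2 these medians were -0.57 for checkpoints and -0.94 for class II, and the log2 fold change of Icos was -1.73. Those of Cd74, H2-Ab1 and Ciita were -1.24, -1.01 and -1.13 without it and -2.16, -1.94 and -3.03 with it. MHC class I genes were lower in 15 of 15 members (median -1.03, camera adjusted p = 0.00029, adjusted p = 0.728 with an estimated correlation), with B2m at -1.03 ± 0.41 and Tap1 at -1.61 ± 0.65. That call was lost without sensitive tumour 2, where the median was -0.42 (camera adjusted p = 0.054), B2m had a log2 fold change of -0.60 and Tap1 one of -0.74. Dendritic cell genes were lower in 11 of 13 members, with Siglech at -3.29 ± 0.76 and a median of -1.45 (camera adjusted p = 0.0113, adjusted p = 0.728 with an estimated correlation). That median was -0.36 without sensitive tumour 2, and the call was lost (camera adjusted p = 0.165).

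Sensitive tumour 2 stood apart from the other 5. Immunoglobulin genes took 3.28% of its counts and between 0.002% and 0.042% in the others. Among them, Ighg2c stood at 4907 CPM there and at 91.4 CPM or less elsewhere, and Jchain, which joins secreted immunoglobulins, at 1536 CPM and at 10.7 CPM or less. The list of B and plasma cells was lower in resistant tumours in 9 of 9 tested members, with a median log2 fold change of -7.00 (camera adjusted p = 0.00045, adjusted p = 0.728 with an estimated correlation). Without that tumour the median was -1.25 (camera adjusted p = 0.0018), and with a block on the replicate number it was -4.36. The first principal component, with 58.1% of the variance, placed this tumour at -109.4 and the others between -23.2 and 83.5.

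The 13 mitochondrially encoded genes were all lower in resistant tumours, with a median log2 fold change of -0.92 (camera adjusted p = 2.5e-06, and adjusted p = 0.708 with an estimated correlation). They took 16.4%, 9.71% and 8.08% of the counts in sensitive tumours 1 to 3 and 7.04%, 8.11% and 5.60% in the resistant tumours, so that the groups overlapped in this share. Without sensitive tumour 1, which has the highest share, the list's median was -0.35 (camera adjusted p = 0.00045). That tumour also had the most RNA of the muscle gene Acta1 (469.5 CPM). Resistant tumour 1 came next in Acta1 (89.3 CPM) with a share of 7.04%. Whether host tissue bears on the share was not tested. The subunit genes mt-Nd2 and mt-Nd5 of respiratory complex I had log2 fold changes of -1.21 ± 0.34 and -1.31 ± 0.47, and mt-Nd5 one of -0.69 without sensitive tumour 1. The ATP synthase subunit gene mt-Atp8 (ENSMUSG00000064356, mitochondrial genome, 7766 to 7969) stood further apart, at 5323 ± 1136 against 1232 ± 326.1 CPM, a log2 fold change of -2.11 ± 0.30 (adjusted p = 0.510, edgeR). It overlaps mt-Atp6 on the same strand, so the reads of the overlap can be counted for either gene.

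Nuclear genes of oxidative phosphorylation lay the other way, higher in 32 of 34 members with a median log2 fold change of 0.29 (camera adjusted p = 6.7e-09, and adjusted p = 0.708 with an estimated correlation). Cox5b, a subunit of cytochrome c oxidase, had a log2 fold change of 0.54 ± 0.13 and Ndufa2, a subunit of complex I, one of 0.66 ± 0.16. None of the 34 passed in edgeR's quasi-likelihood test, over all genes or over the list alone, and DESeq2 called 2 over all genes. Ribosomal protein genes were higher in 28 of 28 members, with a median of 0.36 (camera adjusted p = 1.4e-11, and adjusted p = 0.708 with an estimated correlation). In edgeR's quasi-likelihood test none of the 28 passed over all genes tested, and 13 passed when adjusted over the list alone. DESeq2 called 4 of them over all genes. Rps19 stood at 130.8 ± 13.1 against 226.5 ± 17.8 CPM, Rps20 at 138.6 ± 12.2 against 216.8 ± 10.4 CPM and Rplp1 at 284.4 ± 41.4 against 445.6 ± 32.8 CPM, and Rpl23 had a log2 fold change of 1.00 ± 0.22. Corrected for gene length and GC content, the ribosomal protein median was 0.27 and that of oxidative phosphorylation 0.20, with Ndufa2 at 0.37 and Rplp1 at 0.27 against 0.65 without the correction. Cholesterol synthesis genes were higher in 17 of 19 members (median 0.45, camera adjusted p = 2.9e-06, adjusted p = 0.708 with an estimated correlation), with Lss at 0.59 ± 0.19 and Fdps at 0.66 ± 0.25, or 0.42 without resistant tumour 3. In each of these 3 lists the scores of all 3 resistant tumours lay above those of all 3 sensitive tumours.

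Glycolysis genes were higher in 18 of 18 members (median 0.25, camera adjusted p = 0.00086, adjusted p = 0.728 with an estimated correlation), with Pgk1 at 0.55 ± 0.22 and Ldha at 0.37 ± 0.18. This call was lost without sensitive tumour 2, with a median of 0.16 and a camera adjusted p of 0.0927. Without resistant tumour 2 the median was also 0.16, and the call held (camera adjusted p = 0.0379). The lists of cell cycle genes (24 of 32 higher, median 0.16, Cdk1 at 0.44 ± 0.23), serine, one-carbon and nucleotide synthesis (17 of 17, median 0.17, Phgdh at 0.33 ± 0.23) and MYC targets (18 of 19, median 0.13, Fbl at 0.42 ± 0.24) were called as higher at camera adjusted p values of 0.0179, 0.0267 and 0.0267. With an estimated correlation the adjusted p was 0.812 for the cell cycle and 0.785 for the other two. All 3 calls were lost without sensitive tumour 2, where the medians were -0.02, -0.01 and -0.04 (camera adjusted p = 0.618, 0.895 and 0.739) and Cdk1, Phgdh and Fbl had log2 fold changes of 0.24, 0.18 and 0.22, and without resistant tumour 1 (medians 0.14, 0.13 and 0.09, camera adjusted p = 0.0898, 0.170 and 0.170) or resistant tumour 3 (medians 0.09, 0.11 and 0.06, camera adjusted p = 0.106, 0.106 and 0.103). The medians were larger without sensitive tumour 3 (0.33, 0.39 and 0.31) or resistant tumour 2 (0.25, 0.32 and 0.26), and for MYC targets without sensitive tumour 1 (0.22) and with library-size scaling (0.22). The call of MYC targets was also lost with the length and GC correction, where the median was no smaller (0.15, camera adjusted p = 0.0519).

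Of the 10 receptors that lenvatinib inhibits, 8 were tested and Fgfr3 and Fgfr4 were too low. None of the 8 passed. Kdr, which encodes VEGF receptor 2 (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), stood at 51.0, 77.3 and 34.8 CPM in the sensitive tumours and at 17.9, 33.4 and 25.8 CPM in the resistant ones, a log2 fold change of -1.08 ± 0.35 (adjusted p = 0.510, edgeR). The log2 fold changes were -0.39 ± 0.19 for Flt1, -1.10 ± 0.46 for Ret, -0.56 ± 0.58 for Kit, 0.31 ± 0.42 for Pdgfra, 0.03 ± 0.48 for Fgfr1 and -1.92 ± 1.28 for Fgfr2. Flt4, the VEGF receptor of lymphatic vessels, had one of -1.67 ± 0.86 that rested on sensitive tumour 2, at 42.1 CPM against 5.11 to 6.09 CPM in the other 5. Without that tumour the log2 fold change was 0.09 for Flt4, -0.85 for Fgfr2 and 0.31 for Kit. It was -0.92 for Kit without sensitive tumour 3, -3.83 for Fgfr2 without resistant tumour 3 and -0.19 for Flt1 without sensitive tumour 1. Those of Fgfr1 and Pdgfra turned negative when resistant tumour 2 was left out (-0.35 and -0.13), and that of Fgfr1 also without sensitive tumour 3 (-0.29). The list was called as lower (median -0.82, camera adjusted p = 0.0359, adjusted p = 0.728 with an estimated correlation), and the call was lost without sensitive tumour 2 (median -0.17, adjusted p = 0.389) and without resistant tumour 1 (median -0.81, adjusted p = 0.138). It was also lost with no filter on low counts (median -0.79, adjusted p = 0.0778) and with the length and GC correction (median -0.75, adjusted p = 0.0553). Endothelial genes, Kdr among them, were lower in 20 of 21 members (median -0.65, camera adjusted p = 0.0010, adjusted p = 0.728 with an estimated correlation), with Eng at -0.69 ± 0.21 and Cdh5 at -0.84 ± 0.30. Without sensitive tumour 2 that median was -0.22 and the call was lost (camera adjusted p = 0.190).

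The list of hepatocyte and oncofetal genes was lower in 17 of 22 members (median -0.32, camera adjusted p = 0.0092, adjusted p = 0.708 with an estimated correlation). Its oncofetal members Afp and Gpc3 did not fall, though the groups overlapped. Afp stood at 14.0, 11.5 and 18.6 CPM in sensitive tumours 1 to 3 and at 18.8, 16.7 and 22.8 CPM in resistant tumours 1 to 3. Gpc3 stood at 10.1, 9.13 and 3.26 CPM and at 5.47, 16.1 and 19.3 CPM. Alb, the gene of serum albumin (ENSMUSG00000029368, chromosome 5, 90460897 to 90476602), stood at 183.6 ± 15.5 against 117.9 ± 5.10 CPM, a log2 fold change of -0.64 ± 0.11, and Apob had one of -0.82 ± 0.24. Krt8, a keratin of simple epithelia (ENSMUSG00000049382, chromosome 15, 101996698 to 102004482), went the other way, at 163.0 ± 24.6 against 364.3 ± 111.1 CPM, with a log2 fold change of 1.16 ± 0.26. By edgeR's quasi-likelihood test 2 members passed when adjusted over the list alone and none over all genes, where DESeq2 called 2. Drug metabolism genes were lower in 9 of 12 members (median -0.78, camera adjusted p = 0.0267, adjusted p = 0.708 with an estimated correlation), with Cyp3a11, a cytochrome P450 that oxidises many drugs, at 7.48 ± 0.88 against 3.73 ± 0.74 CPM. Its members Fmo1 and Cyp2e1 were, like the fat cell marker Adipoq, highest in sensitive tumours 1 and 2 and lowest in resistant tumour 1. Cyp2e1 stood at 278.1, 238.4 and 28.4 CPM in sensitive tumours 1 to 3 and at 9.09, 95.5 and 74.3 CPM in resistant tumours 1 to 3, Fmo1 at 42.3, 55.7 and 5.94 and at 1.49, 12.2 and 9.75 CPM, and Adipoq at 196.7, 193.2 and 55.3 and at 2.62, 89.3 and 57.1 CPM. The hepatocyte call was lost without sensitive tumour 2 (median -0.19, camera adjusted p = 0.0860) and without resistant tumour 2 (median -0.27, 0.0504). The call for drug metabolism was lost without sensitive tumour 1, sensitive tumour 2 or resistant tumour 1 (medians -0.86, -0.55 and -0.57, camera adjusted p = 0.0870, 0.0860 and 0.0867), and with no filter on low counts (median -0.67, camera adjusted p = 0.0592).

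**Figure D2:**
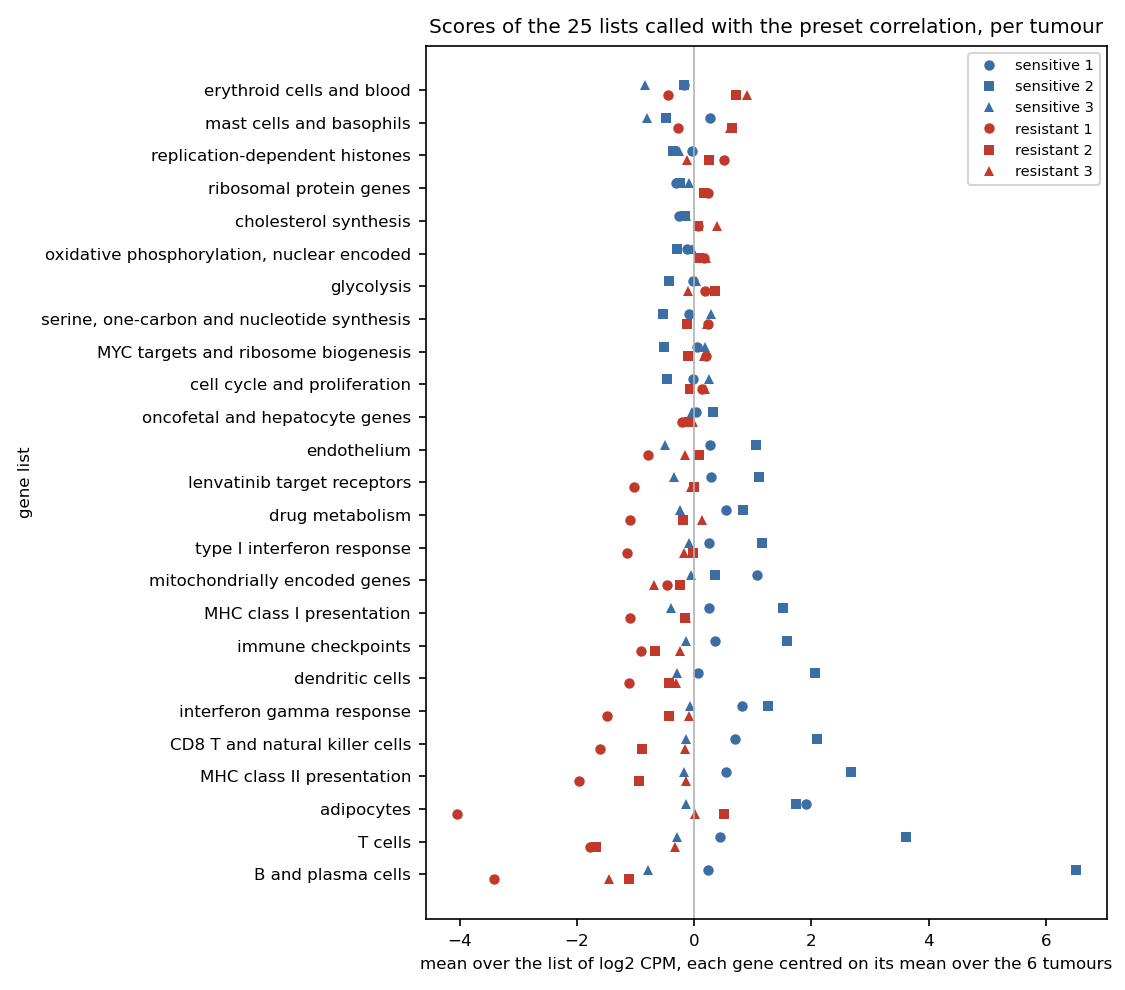
Scores of the 25 lists called with the preset correlation, 1 row per list, as the mean log2 CPM of the list's genes after centring each gene over the 6 tumours, with sensitive tumours in blue, resistant tumours in red and the marker shape giving the tumour number. Sensitive tumour 2 lies far to the right in the lists of B and plasma cells (6.52) and T cells (3.61), while the ribosomal protein scores run from -0.30 to -0.08 in the sensitive and from 0.17 to 0.23 in the resistant tumours.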

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

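Robust dispersions, sample quality weights (in limma-voom), the fits without immunoglobulin and T cell receptor genes or without mitochondrially encoded genes, and the length and GC correction were chosen after seeing the data. The count of 0 genes past the threshold held in edgeR's quasi-likelihood test under each scaling, filter and tumour left out (0 higher and 0 lower), with robust dispersions, with limma-voom and with the length and GC correction. DESeq2 called 117 genes (48 higher, 69 lower) and edgeR's exact test 42 (11 higher, 31 lower). The 3 fits to FPKM called 1 gene each, which was lower: Trbd1, a T cell receptor segment chosen after its value was seen. Its log2 fold change was -2.54 at a pseudocount of 1 and -5.62 at 0.1, so the pseudocount largely set its size. FPKM divides by gene length, so a short segment can reach such values from few reads. The call is therefore not read as a T cell receptor difference. Limma-voom with sample quality weights called 6 (1 higher, 5 lower), namely Per1, Tmem168, Rab22a, Ywhah, mt-Atp8 and Vma21. Genes at an unadjusted p under 0.05 numbered 1404, 1081 by limma-voom, and 2737 by limma-voom with quality weights, which gave sensitive tumour 2 a weight of 0.242. With single tumours left out they ran from 631 (without resistant tumour 1) to 2666 (without sensitive tumour 3). No label says that the replicate numbers pair the tumours. The correlations of same-numbered deviations were 0.05, 0.31 and -0.16, which with 3 tumours a group cannot exclude a pairing. The replicate block gave 0 genes past the threshold (0 higher, 0 lower), 1120 at an unadjusted p under 0.05 and 25 lists.

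Lists called numbered 25, 0 with the correlation estimated per list, and from 14 (without sensitive tumour 2) to 29 (without sensitive tumour 1) with single tumours left out. Of the 25 lists, 12 kept their call in every other alternative that tests them: T cells, CD8 T and natural killer cells, B and plasma cells, both interferon lists, checkpoints, MHC class II, fat cells, mitochondrially encoded genes, ribosomal proteins, nuclear oxidative phosphorylation and cholesterol synthesis. Over the alternatives for the 25 lists, 339 of 397 values kept direction and call, 56 lost the call and 2 reversed in camera's direction, both without sensitive tumour 2: the cell cycle list (median -0.017, and from there to 0.328 with single tumours left out) and MYC targets (-0.043, to 0.311). The median of the serine list also lay below 0 there (-0.007), with camera's direction kept. Of 1549 values of the 68 named genes, 1492 kept direction and side of the threshold, 50 passed it, chiefly in DESeq2 and the exact test, and 7 reversed. The reversals in log2 fold change were Flt4 (0.091) and Kit (0.31) without sensitive tumour 2, Kit with quality weights (0.037), Fgfr1 without sensitive tumour 3 (-0.29), without resistant tumour 2 (-0.35) and with quality weights (-0.20), and Pdgfra without resistant tumour 2 (-0.13). With single tumours left out, Flt4 ran from -2.10 to 0.091, Kit from -0.92 to 0.31, Fgfr1 from -0.35 to 0.34 and Pdgfra from -0.13 to 0.65. The cause of these differences was not tested. In counts simulated at this depth and spread, 6 of 50 genes changed 2-fold were called and 32 of 50 changed 4-fold, against 27 and 49 with 0.25 of the dispersion. The spread between tumours thus limits these calls at the same depth.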

Other observations

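The test of whether sensitive tumour 2 alone makes the T cell difference was chosen after its result had been seen, and the correction for gene length and GC content and the fits without mitochondrially encoded genes were added after seeing the data. Host tissue other than lymphocytes also differed between single tumours. Fat cell genes were lower in resistant tumours in 11 of 11 tested members (median log2 fold change -1.63, camera adjusted p = 0.00029, adjusted p = 0.728 with an estimated correlation), with Car3 at -2.06 ± 1.04 and Lpl at -1.63 ± 0.91 (SE), or -2.54 without resistant tumour 2. Resistant tumour 1 lay lowest: Adipoq stood at 2.62 CPM there, at 57.1 and 89.3 CPM in the other resistant tumours and at 55.3 to 196.7 CPM in the sensitive ones. Skeletal muscle genes were high in sensitive tumour 1, where Acta1 stood at 469.5 CPM, and resistant tumours 1 and 2 followed with 89.3 and 27.2 CPM, while the other 3 tumours had 0.66 CPM or less. That list was not called (camera adjusted p = 0.587), and its mean score was higher in resistant tumours although its median log2 fold change was -1.80. It was called as higher without sensitive tumour 1 (median 5.09, camera adjusted p = 1.4e-05) and without resistant tumour 3 (median -1.36, camera adjusted p = 0.0273), both with the preset correlation. With the correlation estimated (0.93) and all 6 tumours its adjusted p was 0.931.

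Blood and mast cell genes lay the other way. Globin and other erythroid genes were higher in 5 of 6 members (median 1.41, camera adjusted p = 0.0214, adjusted p = 0.718 with an estimated correlation), with Hbb-bs at 14.3 ± 5.61 against 39.4 ± 19.8 CPM and Hba-a2 at 3.99 ± 0.80 against 10.1 ± 4.30 CPM. That call was lost without sensitive tumour 3, resistant tumour 2 or resistant tumour 3 (medians 1.21, 1.12 and 1.27, camera adjusted p = 0.126, 0.108 and 0.103) and with the length and GC correction (median 1.26, camera adjusted p = 0.0519). Mast cell and basophil genes were higher in 9 of 9 members (median 0.51, camera adjusted p = 0.0107, adjusted p = 0.708 with an estimated correlation), with the basophil protease Mcpt8 at 3.30 ± 1.30 against 7.003 ± 1.49 CPM. That call was lost without sensitive tumour 2, sensitive tumour 3 or resistant tumour 2 (medians 0.36, 0.34 and 0.29, camera adjusted p = 0.0564, 0.0729 and 0.0552), and the median was 1.11 without sensitive tumour 1 and 0.94 without resistant tumour 1. Replication-dependent histone genes were higher in 5 of 6 members (median 0.59, camera adjusted p = 0.0063, adjusted p = 0.708 with an estimated correlation), with Hist1h1c at 0.82 ± 0.16. That call was lost without resistant tumour 1 (median 0.27, camera adjusted p = 0.0991) and with the correction for length and GC content (median 0.34, camera adjusted p = 0.125), and the median was 0.36 without resistant tumour 2 and 0.93 without resistant tumour 3. Among the 31 lists not called, the heat shock response (12 of 14 higher, camera adjusted p = 0.0522), the hypoxia response (15 of 21 higher, 0.0669), macrophages and monocytes (10 of 17 lower, 0.238) and drug efflux transporters (5 of 9 lower, 0.709) had median log2 fold changes of 0.27, 0.26, -0.13 and -0.12. With an estimated correlation their adjusted p values were 0.749, 0.757, 0.877 and 0.877. With the preset one, single tumours decided much of this. Heat shock was called as higher without sensitive tumour 1, sensitive tumour 3 or resistant tumour 3 (medians 0.25, 0.43 and 0.40), and its median was 0.005 without sensitive tumour 2 and 0.08 without resistant tumour 2. Hypoxia was called as higher without sensitive tumour 1 or resistant tumour 3 (medians 0.43 and 0.46), with 0.04 without resistant tumour 2. Macrophages and monocytes were called as lower without resistant tumour 2 (median -0.38), with 0.20 without sensitive tumour 2 and 0.17 without resistant tumour 1. Heat shock and hypoxia were also called with no filter on low counts and on log2(FPKM + 1), and heat shock with library-size scaling and with the length and GC correction. Drug efflux ran from -0.33 to -0.02 with single tumours left out and was called in no alternative.

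The lymphoid RNA of sensitive tumour 2 may come from organised lymphoid tissue such as a lymph node in the sample. Of 7 genes chosen for lymph node stroma before their values were read, 4 are listed. The median log2 ratio of this tumour to the highest of the other 5 was 4.42 over the 4 listed, with 3 of them higher. Ccl21a, Ccl19 and Fdcsp are not listed, for a reason not given, so the median leaves them out. Had they been left out for having hardly any reads, they would count against such tissue. Cr2 stood at 42.6 CPM against 0.06 CPM or less elsewhere, Glycam1, a product of the vessels through which lymphocytes enter nodes, at 53.3 against 0.19 CPM or less, and Cxcl13 at 85.5 against 42.5 CPM or less. B cells also make Cr2, and B cell genes were high in this tumour, so Cr2 does not part stroma from B cells. Madcam1 was not higher, at 0.58 against 0.72 CPM in resistant tumour 2, and over so few genes the 95% bootstrap interval of the median ran from -0.30 to 8.15. The test does not part a node taken along with the tumour from lymphoid tissue that formed within it, and no biological explanation was tested, since the labels give this tumour no group of its own.

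Without sensitive tumour 2 the T cell list kept a median log2 fold change of -1.15 (95% bootstrap interval over genes -1.59 to -0.90) and the interferon gamma list one of -1.11. That interval holds no spread between tumours: over the 5 tumours the differences of scores were -1.33 (95% interval -3.44 to 0.79) and -1.05 (-3.08 to 0.99), and sensitive tumour 3 and resistant tumour 3 had near-equal scores (-0.30 and -0.32, -0.07 and -0.09). A part of sensitive tumour 2 alone and a difference between the groups therefore cannot be told apart with so few tumours. The median of 10 interferon gamma genes that tumour and stromal cells also make was -0.96 without that tumour (interval -1.14 to -0.64), which decides nothing on a lower number of T cells alone, because T and natural killer cells make interferon gamma and Ifng itself was lower. Fewer such cells, a weaker signal from each, the drug itself, the resistance and chance differences between 3 tumours a group cannot be told apart by this design.

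After each library was corrected for its trend of counts with gene length and GC content, which could make such differences, the ribosomal protein median was 0.737 of its uncorrected size (interval 0.545 to 0.991), the oxidative phosphorylation median 0.696 (0.545 to 0.976) and the median of the mitochondrially encoded genes 1.04 (0.859 to 1.13), and camera with the preset correlation still called all 3 lists. These intervals are over genes and hold no spread between tumours. The lengths used are not those of single transcripts: Rps19 has 5858 bp, more than its gene spans on chromosome 7 (24884371 to 24889806). For the ribosomal protein and oxidative phosphorylation lists, the trend with these lengths is therefore not the whole of the difference, though it may hold part. The trend was fitted without the mitochondrially encoded genes. Their value therefore decides little, because it carries over a trend learnt on other genes. Whether a trend with transcript length makes the first and second was not tested. Leaving out the mitochondrially encoded genes left the ribosomal protein median at 1.04 times its size (interval 1.03 to 1.06), which decides nothing, because TMM scaling already allows for counts taken up by mitochondrial RNA. With scaling by library size alone, which does not, the median without these genes was 0.838 of that with them (interval 0.801 to 0.878), so counts they took up hold only a small part of the difference there. RNA quality, host tissue in single tumours, reads shared with ribosomal protein pseudogenes, the drug itself and resistance itself stay open and were not tested.

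The 6 tumours can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1404 genes at an unadjusted p under 0.05, and the highest of the other splits gave 2593, so 2 of the 10 splits reached the real count. That highest split set sensitive tumours 1 and 2 with resistant tumour 2 against the rest. For genes past the adjusted threshold the real count of 0 was reached in all 10 splits, the highest other being 2. For lists called with the preset correlation the real count was 25 and the highest other 30, with 3 of the 10 splits at or above the real one. Every split called at least 8 lists, so a call with the preset correlation does not by itself tie a list to resistance in these tumours.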
